A study of Mus musculus with 12 samples.

How the data were processed

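Total RNA of 12 whole-heart samples was labelled with biotin and hybridised to Illumina beadchips, with 6 exercised and 6 sedentary samples assigned from the labels. The authors deposited a table of bead intensity per probe and array that was not normalized, per the file headers, together with a detection p-value for each intensity, per the file headers. The authors also deposited a table of processed values on a scale close to log2, for which the submitters' processing notes name lumi without a version. The deposited values have quartiles that match between arrays within 0.0013, and their slope against the log2 intensity of exercised replicate 1 rises from 0.68 at low to 0.98 at high signal; the transformation is not given in the sources used here. Array medians of the deposited values were all between 6.9836 and 6.9846.

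Intensities were corrected for background with limma's neqc, which took the background from the detection p-values, with an offset of 16, followed by quantile normalization between arrays. Probes with a detection p under 0.01 on at least 6 of 12 arrays were kept, 17098 of 45281. Gene names came from the platform annotation and were compared through gene identifiers with a RefSeq table, which renamed 0 symbols; 34885 probes had 1 symbol, 18 several and 10378 none. Of the probes kept, 14822 had 1 symbol, and the probe with the highest mean was used for each of 9843 genes. No coordinates are given.

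Exercised minus sedentary was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 52 in number, covering pathways and cell types of the heart and neighbouring tissues, were fixed before the data were examined, as were the test, the rule for named genes and the other settings to be tried. The 47 lists with at least 5 measured genes were tested with limma's camera, with a preset correlation of 0.01, and again with an estimated correlation and with fry. List means per array were compared with exact two-sided permutation tests over 924 assignments. Named genes were the 12 largest changes in each direction past the threshold, or, with fewer than 8, those of smallest p up to 8; up to 4 members of each list discussed; and a panel of 22 genes, of which 20 were measured.

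On simulated data with 200 changed genes among 9843, limma recovered 51.8% of genes changed 1.5-fold, 87.3% of those changed 2-fold and 97.3% of those changed 3-fold, and 4.5% of calls were false. The simulated noise was independent between genes and carried no background or liver structure. These shares therefore do not give the error rates on the real arrays.

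The 5th percentile of the raw signal divided the arrays at 75 into 8 with low and 4 with high background, and with the group in the fit 3474 genes differed between them. No slide or scan date is given in the sources used here. The alternatives tried were other background corrections and normalizations, the deposited values, other filters and probe rules, other variance settings, array weights, a replicate block and leaving out each array. Fits with the background range or the liver list mean as terms, or within subsets of arrays, were chosen after seeing the data.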

Results

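Gene expression was measured in whole hearts of male C57Bl/6 mice aged 8 weeks, in 6 samples after 7 days of voluntary wheel running and 6 sedentary controls. Each sample was hybridised to an Illumina mouse beadchip with 45281 probes, and 9843 named genes were detected on at least 6 of the 12 arrays. Between 16619 and 18708 probes per array were detected, with a mean of 17467 ± 810 in exercised and 17239 ± 344 in sedentary hearts (SD, n = 6). The number of arrays limits the precision of each value. Raw signals fell into a low and a high range, with medians of 48.6 to 53.3 on 8 arrays and 130.5 to 138.6 on 4 arrays, namely exercised replicates 2, 3 and 6 and sedentary replicate 2. The labels number the replicates within each group and do not say that each is a separate animal, so p-values measure the spread between these samples.

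The comparison of exercised with sedentary hearts addressed which cardiac transcripts respond to a week of running. The interferon-induced genes Isg15, Ifit3 and Oasl2 fell by 0.97, 0.72 and 0.74 on the log2 scale, and Cd74 and H2-Eb1, which serve antigen presentation by class II molecules, fell by 0.69 and 0.77. Further passing probes gave smaller differences for Ifit3 (-0.39, SE 0.22) and Oasl2 (-0.31, SE 0.16), and similar values for Cd74 (-0.70 and -0.74). Fcgr4, an Fc receptor of myeloid cells, fell by 1.23 (SE 0.21), and Cd14, a co-receptor for bacterial lipopolysaccharide, fell by 0.72 (SE 0.13). Fos, a subunit of the transcription factor AP-1, was at 6.03 ± 0.37 in exercised and 7.44 ± 0.43 in sedentary hearts (log2 intensity, SD, n = 6).

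In limma, 18 of the 9843 genes changed at an adjusted p under 0.05, of which 2 were higher and 16 lower in exercised hearts. The smallest adjusted p belonged to 2210407C18Rik (0.0006 in limma), which fell by 1.26 (SE 0.13) and lay below every sedentary array in 6 of 6 exercised arrays. The genes that rose were Abcb4, a phospholipid transporter, by 0.63 (SE 0.10), and Ahrr, the repressor of the aryl hydrocarbon receptor, by 0.61 (SE 0.11). The others that fell were Acta2, the smooth muscle actin, by 0.70 (SE 0.12), Slamf9 by 0.86 (SE 0.15), Timeless by 0.75 (SE 0.14), the complement gene C1qb by 0.66 (SE 0.12) and Ly6c1 by 0.44 (SE 0.07). Cxcl1, a chemokine, and Pde4b, a phosphodiesterase, fell by 0.68 each and lie outside the rule for named genes. Another passing probe of Pde4b gave -0.19 (SE 0.19), while those of Acta2 gave -0.77, -0.81 and -0.87. Among the genes nearest to the threshold on the higher side, Scin differed by 0.81 (SE 0.17) and Abat by 1.07 (SE 0.24), with adjusted p of 0.070 and 0.094 in limma; Abat was at 0.65 with the liver list mean as a covariate and at 0.71 without the 3 arrays richest in liver transcripts. At an unadjusted p under 0.01 there were 479 genes, against 98.43 given by chance. The count of 18 genes in limma became 36 with the background range of the arrays as a block and 10 within the 8 low-background arrays. The 4 high-background arrays held 3 exercised arrays and 1 sedentary array. Within them the log2 fold changes of the 18 genes were 0.26 to 1.15 times as large (median 0.76). The count was 1 with the liver list mean as a covariate, 533 with array weights, 9 with cyclic loess and 1 without a filter. It was 0 with median scaling, where 83 genes had an unadjusted p under 0.01, below the 98.43 given by chance. At an unadjusted p under 0.05 there were 432 with median scaling, also fewer than chance gives. Of these 355 were higher, against 521 of 1565 with quantile normalization. With the liver covariate the log2 fold changes of the 18 genes were 0.74 to 1.22 times as large (median 0.99) and their SE 1.04 to 1.30 times (median 1.25), with Fos at -1.33 (SE 0.26), Isg15 at -1.18 (SE 0.19), Fcgr4 at -1.42 (SE 0.25) and Abcb4 at 0.46 (SE 0.11). With median scaling they were 0.31 to 1.56 times as large (median 0.56) and their SE 1.13 to 3.40 times (median 2.01). The count of changed genes was 3 with a replicate block. It was 2, 1, 1, 2, 1 and 1 without exercised replicates 1 to 6 and 17, 236, 3, 1, 1 and 2 without sedentary replicates 1 to 6. Without sedentary replicate 2 the high-background range held exercised arrays alone, so the 236 genes may mix background with group. 2210407C18Rik passed the threshold in all 12 fits that left out an array.

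**Figure D1:**
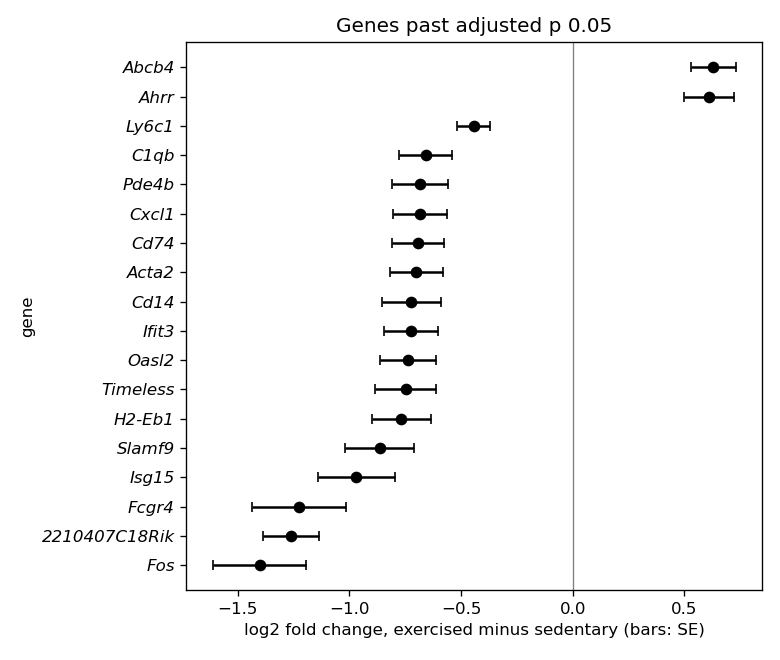
Log2 fold change (x axis, exercised minus sedentary, bars are SE from limma, n = 6 per group) of the 18 genes past an adjusted p of 0.05, by gene (y axis). Abcb4 and Ahrr lie above 0 and the other 16 genes below it, down to -1.40 for Fos.

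Interferon-stimulated genes were lower as a group. Of 25 measured members, 24 had a negative log2 fold change, with a median of -0.41. In limma, 3 fell over all genes tested and 18 fell when adjusted over the list alone. Camera placed the list below other genes (adjusted p = 4.2e-13, and adjusted p = 0.0052 with an estimated correlation). The list mean was 7.89 ± 0.08 in exercised and 8.34 ± 0.06 in sedentary hearts (SD, n = 6; exact two-sided permutation p = 0.00216, the smallest that 924 assignments can give, and 0.020 adjusted over the 47 lists), and all 6 exercised arrays lay below every sedentary array. The median was -0.45 with the background block, -0.49 within the low-background arrays and -0.28 within the high-background arrays, where 3 exercised arrays faced 1 sedentary array. With an estimated correlation the adjusted p of camera was 0.0030 with the block and 0.012 within the low-background arrays.

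Antigen presentation genes of class I and II also shifted down, with 16 of 17 members negative and a median of -0.42. In limma, 2 members fell over all genes and 13 when adjusted over the list alone, among them H2-Ab1 (-0.84, SE 0.18) and H2-DMa (-0.61, SE 0.14) in the second count. The camera call (adjusted p = 1.9e-10) held with an estimated correlation (adjusted p = 0.017). The list mean was 8.27 ± 0.09 against 8.77 ± 0.14 (SD, n = 6; exact two-sided permutation p = 0.00216, adjusted 0.020). Its median was -0.45 with the background block, -0.46 within the low-background arrays and -0.51 within the high-background arrays, where the sedentary group is 1 array. With an estimated correlation the adjusted p of camera was 0.020 with the block and 0.20 within the low-background arrays, where the call was lost.

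Macrophage markers were negative in 19 of 19 measured genes, with a median of -0.66. C1qb and Cd14 fell in limma over all genes and 16 members fell when adjusted over the list alone. The list was called by camera (adjusted p = 4.6e-12), and the call was lost with an estimated correlation (adjusted p = 0.20 with an estimated correlation). The list mean was 8.31 ± 0.24 in exercised and 8.90 ± 0.33 in sedentary hearts (SD, n = 6; exact two-sided permutation p = 0.013, adjusted 0.068), with 3 of 6 exercised arrays below every sedentary array. Its median was -0.44 with the background block, -0.48 within the low-background arrays and -0.31 within the high-background arrays, again with 1 sedentary array.

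**Figure D2:**
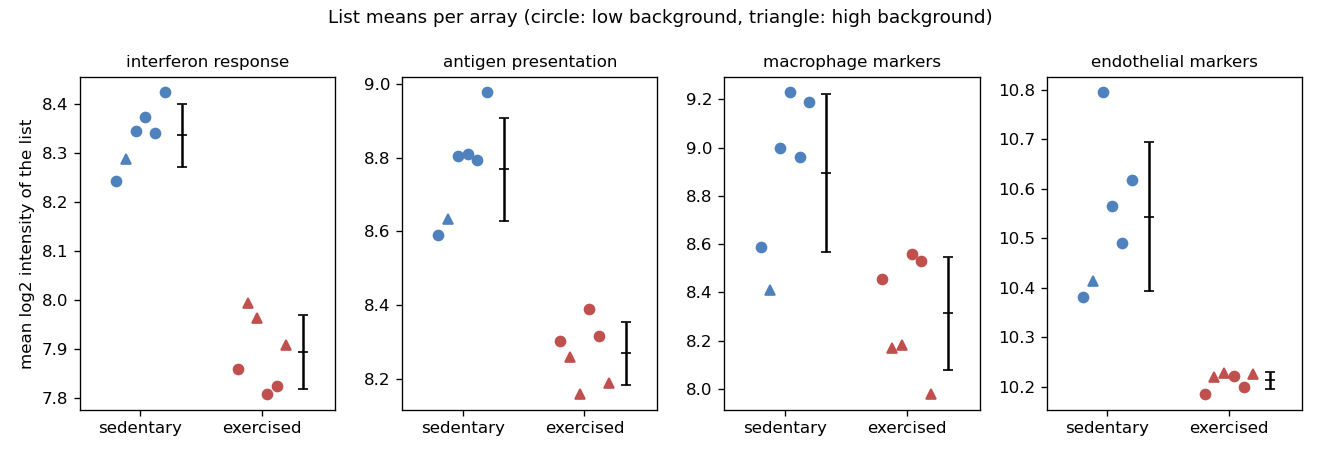
Mean log2 intensity (y axis) of the interferon, antigen presentation, macrophage and endothelial lists per array, by group (x axis); circles are low-background and triangles high-background arrays, and black marks are the mean and SD (n = 6). All 6 exercised arrays lie below every sedentary array for the interferon, antigen presentation and endothelial lists, and 3 of 6 do so for the macrophage list.

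Markers of vessels and connective tissue were lower too, without an estimated-correlation call. Endothelial markers were negative in 15 of 15 genes, with a median of -0.36, and Ly6c1 fell in limma over all genes, 9 adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.12 with an estimated correlation). Smooth muscle and pericyte markers had a median of -0.23 with 11 of 13 negative, and Acta2 fell (camera adjusted p = 0.0041; adjusted p = 0.12 with an estimated correlation). Of 41 matrix genes, 36 were negative with a median of -0.34, 0 were called over all genes and 8 when adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.26 with an estimated correlation). Platelet and mast cell markers were negative in 10 of 10 genes, with a median of -0.47 (camera adjusted p = 0.00015; adjusted p = 0.053 with an estimated correlation). For the endothelial, smooth muscle and platelet lists the mean of all 6 exercised arrays lay below every sedentary array (exact two-sided permutation p = 0.00216, adjusted 0.020 each), and for the matrix list that of 1 did (p = 0.024, adjusted 0.10). Ribosomal protein genes had a median of -0.26 and 45 of 46 were negative, while their mean turned to 0.018 with median scaling, which moved the median of all genes to 0.26 (camera adjusted p = 1.3e-05; adjusted p = 0.43 with an estimated correlation). The ribosomal median was -0.12 with the background block and -0.07 within the low-background arrays, where camera no longer called it (adjusted p = 0.083). Median scaling moved the means of the interferon, antigen presentation, macrophage, endothelial and matrix lists to -0.13, -0.19, -0.26, -0.01 and -0.02, all called by camera. Within the high-background arrays, with 1 sedentary array, the medians were -0.21 for endothelial, -0.19 for matrix and -0.26 for platelet and mast cell genes.

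Lists of mitochondrial biogenesis, glycolysis, fatty acid oxidation, the sarcomere and the clock were shifted up by camera, and none of their members passed the threshold over all genes in limma. In exact two-sided permutation tests of the list means, none of these lists passed after adjustment. In the order given, p was 0.032, 0.091, 0.20, 0.076 and 0.097 (adjusted 0.10, 0.20, 0.33, 0.19 and 0.20). For the sarcomere, 1 of 6 exercised arrays lay above every sedentary array, and for each of the others 2 of 6 did. Genes of oxidative phosphorylation were not shifted, with 17 of 69 positive and a median of -0.05 (camera adjusted p = 0.48). Regulators of mitochondrial biogenesis had a median of 0.20 with 20 of 25 positive (camera adjusted p = 8.8e-05; adjusted p = 0.20 with an estimated correlation), among them Ppargc1a, a coactivator of mitochondrial genes, at 0.51 (SE 0.21) and at 0.26 with the background block. Glycolysis and glucose genes had a median of 0.17 with 26 of 31 positive (camera adjusted p = 0.00011; adjusted p = 0.26 with an estimated correlation), and Slc2a1, a glucose transporter, differed by 0.36 (SE 0.13). Sarcomere genes had a median of 0.14 with 21 of 29 positive (camera adjusted p = 0.00063, and adjusted p = 0.26 with an estimated correlation). Among them were Myom2 at 0.77 (SE 0.17) and Ttn, titin, at 0.43 (SE 0.12). Other passing probes of Ttn gave 0.05 (SE 0.17) to 0.80 (SE 0.34), and the probe used was at 0.31 with the background block. Fatty acid oxidation genes had a median of 0.14 with 27 of 37 positive (camera adjusted p = 0.0017; adjusted p = 0.36 with an estimated correlation), and within the low-background arrays 20 of 37 were positive with a mean of -0.0045, where camera no longer called the list (adjusted p = 0.19). The clock list had 12 of 14 genes positive and a median of 0.12 (camera adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation), with Ciart at 1.07 (SE 0.25). With the background block the medians were 0.13 for mitochondrial biogenesis, 0.10 for glycolysis, 0.08 for the sarcomere and 0.06 for fatty acid oxidation. Within the high-background arrays, with 1 sedentary array, the medians were 0.03 for mitochondrial biogenesis, 0.04 for glycolysis and 0.04 for the sarcomere, whose mean was 0.001, and the clock mean was -0.012. With the block the clock list had 8 of 14 genes positive and a median of 0.007, and camera no longer called it (adjusted p = 0.054), nor within the low-background arrays (adjusted p = 0.080), without the 3 arrays richest in liver transcripts (adjusted p = 0.054) or with median scaling (adjusted p = 0.065).

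Immediate early genes were negative in 20 of 27 members, with a median of -0.17 and a mean that turned to 0.051 with median scaling (camera adjusted p = 0.0073; adjusted p = 0.27 with an estimated correlation). The median was -0.08 with the liver list mean as a covariate. List means were 7.97 ± 0.12 in exercised and 8.20 ± 0.09 in sedentary hearts (SD, n = 6). Their exact two-sided permutation p was 0.0043 (adjusted 0.025), and 5 of 6 exercised arrays lay below every sedentary array. Fos fell in limma over all genes and 5 fell when adjusted over the list alone; Klf2 differed by -0.79 (SE 0.16) and Egr3 by -0.71 (SE 0.16).

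The classical markers of cardiac hypertrophy did not pass the threshold in limma. Nppa, the atrial natriuretic peptide, differed by 0.40 (SE 0.29), Nppb by -0.25 (SE 0.23), Myh7, the slow myosin heavy chain, by 0.37 (SE 0.17), Myh6 by -0.02 (SE 0.09) and Acta1 by 0.00 (SE 0.13). Lists of pathological hypertrophy (median -0.12, camera adjusted p = 0.92) and of physiological growth (median 0.05, camera adjusted p = 0.33) were not called. The hypertrophy list shares 4 measured genes with the atrial marker list, whose mean ranged from 8.69 in sedentary replicate 1 to 10.71 in sedentary replicate 3. Whether this spread hides a change was not tested. Of the 22 panel genes fixed in advance, 20 were measured and Fos passed.

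Liver transcripts were present at very different levels. The liver list mean was 11.06, 12.58 and 13.59 in exercised replicates 1, 5 and 6, between 7.22 and 8.48 in the other 3 exercised arrays and between 6.83 and 8.93 in sedentary arrays. The group means were 10.08 ± 2.70 and 7.49 ± 0.79 (SD, n = 6; exact two-sided permutation p = 0.058, adjusted 0.16). All 8 measured members were positive, with a median of 2.77 (camera adjusted p = 3e-06; adjusted p = 0.26 with an estimated correlation), 0 called over all genes and 8 when adjusted over the list alone in limma. Without these 3 arrays the liver median was 0.19 (camera adjusted p = 0.32). Limma then called 1 gene, while the log2 fold changes of the 18 genes were 0.81 to 1.25 times as large (median 0.99) and their SE 1.06 to 1.39 times (median 1.25), with Fos at -1.38 (SE 0.25), Isg15 at -1.21 (SE 0.18) and Ahrr at 0.66 (SE 0.16). The interferon median was -0.42 and that of antigen presentation genes -0.50, and the adjusted p with an estimated correlation was 0.10 and 0.12.

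**Figure D3:**
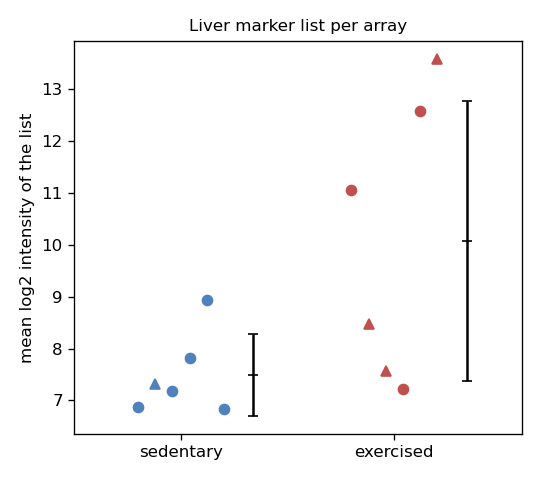
Mean log2 intensity of the liver marker list (y axis) per array, by group (x axis); circles are low-background and triangles high-background arrays, and black marks are the mean and SD (n = 6). Exercised replicates 1, 5 and 6 lie at 11.06, 12.58 and 13.59, above the highest sedentary array at 8.93.

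Over the 47 gene lists tested, camera called 24, of which 11 were shifted up and 13 down. With an estimated correlation 2 remained, those of interferon response and antigen presentation, and fry called 15. The other lists called down by camera were those of fibroblasts, angiogenesis, inflammation and valve cells, with adjusted p of 0.27, 0.26, 0.28 and 0.26 with an estimated correlation. In exact two-sided permutation tests of the list means their adjusted p were 0.10, 0.025, 0.20 and 0.11. Those called up were branched-chain amino acid and ketone catabolism, cholesterol synthesis, cardiomyocytes, the tricarboxylic acid cycle and heat shock proteins, with adjusted p of 0.28, 0.39, 0.26, 0.46 and 0.46 with an estimated correlation. The cholesterol list had a median of 0.21, against 0.03 with the liver list mean as a covariate and 0.05 without the 3 arrays richest in liver transcripts, where camera did not call it (adjusted p = 0.89 and 0.70). Heat shock proteins were not called in these 2 settings either (adjusted p = 0.078 and 0.34), and cardiomyocytes not without those arrays (adjusted p = 0.054). The heat shock list mean was 11.12 in exercised replicate 1 and 10.33 to 10.61 in the other exercised arrays, inside the sedentary range of 10.30 to 10.79. Its group means differed by 0.06 (exact two-sided permutation p = 0.70). With background and liver terms together the cholesterol median was -0.04, and camera did not call the cholesterol, cardiomyocyte and clock lists (adjusted p = 0.73, 0.075 and 0.17). Within the low-background arrays camera did not call the cholesterol, heat shock, cardiomyocyte, tricarboxylic acid cycle, inflammation and valve lists (adjusted p = 0.090, 0.083, 0.083, 0.13, 0.075 and 0.11), and with the background block not the tricarboxylic acid cycle (adjusted p = 0.096). For the glucocorticoid, antioxidant, thyroid hormone, white and brown adipocyte and skeletal muscle lists, which were not called, the median was negative and the direction of camera was up.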

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

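Of the tests below, those on the background, on leaving out the arrays rich in liver transcripts and on the macrophage share were chosen only after the results were seen; the hepatocyte test on measured genes and the splits of the arrays were set before.

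Single arrays stood far from the rest of their group in 10 of 232 groups of values examined, where chance gives about 11.6. These were Ccnd2 at 11.27 in exercised replicate 1, Lyz2 at 10.97 in exercised replicate 1, Cxcl1 at 5.86 in exercised replicate 2, Fkbp5 at 8.32 and Rps7 at 12.67 in exercised replicate 3, Nr2f2 at 4.48 in exercised replicate 4, and Emcn at 11.34, Oasl2 at 8.45 and Rora at 8.93 in sedentary replicate 2 (log2 intensity). Sedentary replicate 2 also had the most detected probes of its group, 17883.

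Liver transcripts were high in exercised replicates 1, 5 and 6. The high background is argued against by 1 of the 4 high-background arrays lying above the highest low-background sedentary array. Liver RNA or liver tissue carried into these samples stays open: of 50 hepatocyte genes listed in advance, 12 were measured, and 66.7% of these had exercised replicate 6 above 5 above 1 above all other arrays, between the bounds of 80% and 50% set for the test. Only genes detected on at least 6 of 12 arrays were measured, so hepatocyte genes present on exercised replicates 1, 5 and 6 alone could not enter. For that reason the share cannot decide on liver RNA or tissue carried over. A response of the exercised hearts was not tested and stays open.

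Interferon, antigen presentation and macrophage lists were lower in exercised hearts, and within the low-background arrays the list means differed by -0.52 and -0.46 for interferon and antigen presentation (exact permutation p = 0.018 each, the smallest possible), and by -0.48 for macrophage markers (exact permutation p = 0.054). With the groups permuted within each background range over all 12 arrays, the differences were -0.46, -0.45 and -0.43 (exact permutation p = 0.0045, 0.0045 and 0.013, with 0.0045 the smallest possible), which argues against the background as the whole cause for each list. Without the 3 arrays rich in liver transcripts the differences were -0.41, -0.50 and -0.59 (exact permutation p = 0.012, 0.012 and 0.048). Of the exercised arrays left, replicates 2 and 3 had high background and replicate 4 low. For interferon and antigen presentation each of them lay below every sedentary array, which argues against liver RNA as the whole cause for these lists. The macrophage mean of exercised replicate 4 was 8.56, against 8.59 in sedentary replicate 1 and 8.41 in sedentary replicate 2. Since liver and background are not parted there, liver RNA stays open for the macrophage list. With the macrophage list mean as a covariate, the mean log2 fold change was -0.43 for interferon and -0.33 for antigen presentation genes. Of these, 23 of 25 and 15 of 16 genes were negative, and both lists passed the threshold of fry. This fit held no background term. The macrophage mean was lowest on the high-background arrays of each group, at 7.98 to 8.18 in exercised and 8.41 in sedentary hearts. The fit therefore cannot decide on a lower share of macrophages alone, which stays open. A lower share of several non-muscle cell types together was not tested and stays open, as does a response of the tissue to running.

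Splits of the 12 arrays into 6 and 6, of which 100 were drawn from 462, gave as many changed genes as the real split in 3 cases, the real split included, and the same holds for the genes higher (3) and lower (3). The real counts were 18, 2 and 16, and the highest other split gave 2002 genes, 1319 in 1 direction and 683 in the other. Since a split has no direction of its own, the larger of these was set against both the higher and the lower genes. Both other splits with as many genes placed all 4 high-background arrays in the same group, which points to a structure of the samples; 4 more splits did so and gave 0 genes in limma, with 552 to 793 at an unadjusted p under 0.01. The count with the background as a block was 36. For the 479 genes at an unadjusted p under 0.01, 7 of 100 splits gave as many and the highest other gave 1986, so chance could not be excluded by this count, which takes no account of the background. The 6 other splits with as many all placed the 4 high-background arrays in the same group; the highest among the 50 other splits that parted them 3 and 1, as the real split does, was 255. For the 24 lists, 1 of 100 splits, the real split, gave as many, and the highest other gave 23. Among splits with 3 exercised arrays in each group, camera called 0 to 17 lists. Camera with the preset correlation thus called lists also where the groups did not differ in exercise, so its adjusted p are too small here.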

How the results depend on the processing

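Settings with the background range, the liver list or subsets of arrays were chosen after seeing the data; the others were planned. The 18 changed genes (2 higher, 16 lower) kept their sign in every setting run, and all 18 were called again without background correction, with a robust fit and among genes detected on all 12 arrays. With the deposited values 16 were called, and Fcgr4 and Pde4b were not (adjusted p = 0.066 and 0.064 in limma). There Fos was at -0.61, Fcgr4 at -0.47, Isg15 at -0.46 and Ahrr at 0.23, while Acta2 was at -0.72 and Ly6c1 at -0.44. The log2 fold changes of the 18 genes were 0.38 to 1.03 times as large with the deposited values (median 0.74) and 0.60 to 1.00 times without background correction (median 0.87). The SE were a median of 0.74 and 0.87 times as large. Limma called 0 genes with median scaling, where the median of all genes moved from -0.04 to 0.26. There 83 genes had an unadjusted p under 0.01, below the 98.43 given by chance, and 432 under 0.05, also fewer than chance gives. Of the 432 genes 355 were higher, against 521 of 1565 with quantile normalization. Limma called 9 genes with cyclic loess (2 higher, 7 lower) and 1 without a filter (0 higher, 1 lower), where 19057 genes were tested. With array weights it called 533 (131 higher, 402 lower, 1065 at an unadjusted p under 0.01). With all probes 15 were called (1 higher, 14 lower) and 735 passed an unadjusted p under 0.01, among 17098 probes tested. With the background block there were 36 (5 higher, 31 lower). Within the low-background arrays there were 10 (0 higher, 10 lower) and 15 lists, and within the high-background arrays 0, with 8 at an unadjusted p under 0.01 and 105 under 0.05, where the lone sedentary sample is assumed to vary like the others. With the liver covariate there was 1 (0 higher, 1 lower; 257 at an unadjusted p under 0.01), with background and liver terms 3 (0 higher, 3 lower; 308) and without the 3 arrays rich in liver transcripts 1 (0 higher, 1 lower; 296). Genes higher in exercised hearts at an unadjusted p under 0.05 numbered 869 without a filter, 493, 567, 535 and 703 in the settings of this group with 0 higher (low background, liver covariate, background and liver terms, liver arrays left out). With the liver covariate, with background and liver terms and without the liver-rich arrays, the log2 fold changes of the 18 genes were a median of 0.99, 0.92 and 0.99 times as large and their SE 1.25, 1.09 and 1.25 times. With median scaling these medians were 0.56 and 2.01. Apart from these values and the smaller number of arrays or larger number of genes in these settings, the cause was not tested.

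Leaving out each array in turn gave 1 to 236 changed genes, 0 to 54 higher, 1 to 182 lower, 275 to 949 at an unadjusted p under 0.01 and 22 to 25 lists. The highest gene counts came without sedentary replicate 2, the only high-background sedentary array, where background and group overlap. Camera called 2 lists with an estimated correlation, and fry 15. The mean of ribosomal genes became 0.018 and that of immediate early genes 0.051 with median scaling, both below the median of all genes there; fatty acid oxidation was at -0.0045 within the low-background arrays and the clock list at -0.012 within the high-background arrays. The liver list has no value with its own mean as a covariate.

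With the replicate block, limma called 3 genes (0 higher, 3 lower; 665 higher at an unadjusted p under 0.05). Same-numbered samples deviated together (correlation over 0.1) in 3 of 6 pairs, and 4 of the 12 samples correlated best with their own number, so the numbers were not taken as a pairing. The slide could not be used as a block, since the sources used here give none. Signal over background limits which genes were tested, since 17098 of 45281 probes passed the detection filter.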

Other observations

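Atrial transcripts differed widely between samples of the same group. The list of atrial markers had a mean of 9.91 ± 0.53 in exercised and 9.68 ± 0.80 in sedentary hearts (SD, n = 6; exact two-sided permutation p = 0.57), and ranged from 8.69 in sedentary replicate 1 to 10.71 in sedentary replicate 3. Hspa1a, an inducible heat shock protein, was at 12.18 in exercised replicate 1 and between 5.84 and 9.49 on the other arrays.

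Lymphatic endothelial markers were negative in 5 of 6 genes, with a list mean of 8.51 ± 0.14 in exercised and 8.76 ± 0.11 in sedentary hearts (SD, n = 6; exact two-sided permutation p = 0.0043, adjusted over the 47 lists 0.025); camera did not call the list (adjusted p = 0.17). Hypoxia-inducible genes had a list mean of 9.22 ± 0.05 against 9.15 ± 0.05 (SD, n = 6; exact two-sided permutation p = 0.032, adjusted 0.10), with Slc2a1 and Pdk1 at 0.36 and 0.40 and Ndrg1 at -0.51. Camera did not call this list either. Slc27a2, a member of the brown adipocyte list that liver also expresses, differed by 2.87 (SE 0.95), and by 0.53 without the 3 arrays richest in liver transcripts and 0.32 with the liver list mean as a covariate.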
